A study of Escherichia coli with 2 samples.

How the data were processed

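Transcript levels were measured on 2 one-colour oligonucleotide arrays of Escherichia coli, 1 for the wild-type strain BW25113 and 1 for its ldhA pflB double knockout. Per the labels' protocols, both strains were grown under limited oxygen in M9 minimal medium with 10 g/L glucose and harvested in the middle of exponential growth, and 6 ug of total RNA entered the labelling reaction with biotin. The deposited table holds 1 intensity per probe set and array, on a linear scale. Per the submitters' processing notes, these intensities are MAS5 signals; the version, the scaling target, any filter and the detection calls are not given in the sources used here. The mean without the lowest and highest 2% of probe sets was 499.9 on the wild-type array and 499.1 on the knockout array, as scaling each array on its own to a common mean would give. Scaling each array to a common mean assumes that most probe sets carry a similar amount of labelled target on the arrays compared.

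The table holds 7312 probe sets, of which 4345 are for genes, 2886 for intergenic regions, 22 for control transcripts, 46 for phage lambda, phage M13 and the F plasmid, and 13 for other sequences. Genes were named through the platform annotation, matched on gene identifiers to the RefSeq table of E. coli K-12 MG1655 (assembly ASM584v2). A gene probe set was used when the annotation gave exactly 1 K-12 gene, which held for 4192 of them; 41 had several, 12 had none and 100 were not listed. These made 4148 genes, and for a gene with several probe sets the one with the highest mean log2 signal was kept. The genome build of the array design is not given in the sources used here, so no coordinates are printed. The transcripts of bioB, bioC and bioD are also used as added controls on such arrays, so the signals of these genes are not read as expression.

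Signals were turned to log2 and used on the deposited scale. Each array was given a floor, the highest signal among the probe sets for genes that strain BW25113 lacks. Of the 6 genes considered (araA, araB, araD, rhaA, rhaB and rhaD), any above the median of all probe sets on an array were left out, which left araA, araB, rhaA and rhaB on both arrays. The floors were 211.8 on the wild-type array and 156.3 on the knockout array. A gene above the floor is called detected, and a signal below the floor was set to it. The log2 ratio is knockout minus wild type, and a ratio with 1 side below the floor is a lower bound. Detection here means only that the signal lay above this floor. It does not show that a transcript was present, since araD, rhaD and lacZ, which are affected by the deletions in BW25113, also lay above it on both arrays.

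With 1 array per strain there is no replicate, so no test between strains was possible, no p-value or standard deviation is given, and a repeat without a doubted array could not be run. The number of arrays limits the precision. Genes are described by the size of their ratio, with a ratio of at least 2-fold (1 on the log2 scale) as the threshold. For 35 gene lists, the median ratio of the detected members was placed among 10000 random lists of the same size, drawn from detected genes in 10 bins of mean log2 signal, and called outside when it lay under percentile 2.5 or above 97.5. The matching is tied to the ratio: across detected genes the mean signal had a Spearman rho of 0.65 with the ratio, 0.94 with the knockout signal and 0.67 with the wild-type signal, so matched lists of highly expressed genes have high ratios themselves (median 1.47 for ribosomal proteins). A place inside the matched range is therefore not read as the lack of a shift, and unmatched lists were an alternative. This percentile describes these 2 arrays, since genes are not replicates of a strain. Of 35 such lists, 1.75 would lie outside by chance if genes moved independently of each other. Adjacent genes did not, with a Spearman rho of 0.53 for their ratios. Lists that hold neighbouring genes can therefore lie outside by chance more often than this. The agreement of adjacent genes was measured by Spearman's rho across genes. The planned split of adjacent genes by strand was not made, because the reference table used gives no strand, so adjacent pairs were set against random pairs. For the fit of intergenic signal along the chromosome, the replication origin was placed between mnmG and mioC by its fraction of the ASM584v2 chromosome, and the terminus opposite to it.

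The floor, the lists, the comparisons and the rule for naming genes were fixed before the data were examined. The tests of explanations in the closing section were set later, as said there. The rule names ldhA, pflB and the genes beside them, the 12 highest and 12 lowest ratios among detected genes, and up to 4 members of each list with the largest absolute ratio. Other genes named were chosen after their values were seen, which is said where they appear. A set of 9 alternatives was fixed at the same time (3 other scalings, 2 other floors, genes detected on both arrays, the mean over probe sets, unmatched random lists and the mean in place of the median). Another 4 were added after seeing the data: a floor at percentile 90 of the intergenic probe sets of each array, a scaling on the hybridization controls, a scaling on the median of the poly-A controls, and the use of unshared protein-coding probe sets alone.

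The scripts were tested on simulated data of 3605 genes for the comparison of knockout with wild type, in which 200 genes of the knockout array were moved by known folds, with noise of 0.3 (SD, log2) on each simulated array. Of the genes moved 4-fold, 98% passed the 2-fold threshold in either direction, and of those moved by exactly the threshold 50% (up) and 48% (down) did. Among unmoved genes 1.12% passed it. A list of 20 genes moved up was placed at percentile 100, a list of 20 genes moved down at percentile 0, and a list of 20 randomly chosen genes at 79.35. Both simulated arrays were drawn from the knockout signals, and the moved and listed genes from those with high knockout signals. The real wild-type array had a much narrower range, so these rates check the scripts and do not hold for the real comparison. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.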

Results

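The study compared the transcript levels of E. coli BW25113, a laboratory K-12 strain, with those of a derivative that lacks ldhA and pflB. ldhA (b1380) encodes the fermentative D-lactate dehydrogenase, and pflB (b0903) encodes pyruvate formate-lyase, which splits pyruvate into acetyl-CoA and formate. Each strain was measured on 1 array, so every value below is a single measurement without a replicate error. The comparison asks how expression differs between the strains during growth on glucose with limited oxygen.

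The signals on the wild-type array spanned a much narrower range than those on the knockout array. Between percentiles 5 and 95, gene signals ran from 285.9 to 920.1 on the wild-type array (3.22-fold) and from 93.99 to 2599 on the knockout array (27.6-fold). The median gene signal was 538.3 on the wild-type array and 317.2 on the knockout array. Intergenic probe sets had medians of 377.1 and 161.1, with a 7.20-fold and a 43.9-fold range between the same percentiles. Probe sets for phage lambda, M13 and the F plasmid, none of which is part of the BW25113 chromosome, had medians of 23.8 and 38.4. Of the genes affected by the deletions in BW25113, rhaA (21.1 and 22.1), araB (32.5 and 32.9) and araA (100.4 and 86.1) were low on the wild-type and knockout arrays. rhaB set the floors (211.8 and 156.3), and araD (804.3 and 326.4) and rhaD (606.3 and 265.8) were above them. The Spearman correlation of gene signals between the arrays was 0.45, taken across genes, which are not independent replicates.

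**Figure D1:**
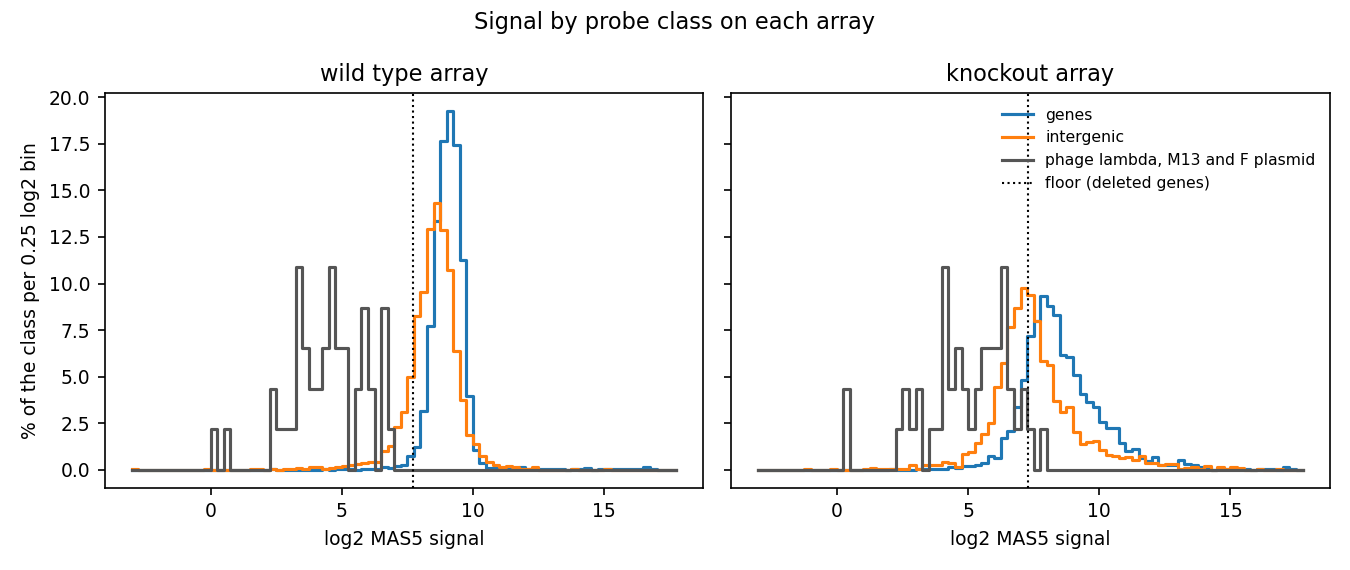
Share of each probe class (vertical axis, percent per bin of 0.25 log2 units) by log2 MAS5 signal (horizontal axis) on the wild-type and knockout arrays; the dotted line is the floor of each array. Genes form a narrow peak on the wild-type array (median 538.3; intergenic probe sets 377.1), and genes spread to high signals on the knockout array.

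The targeted genes were read first, as a check of the labels; which part of each gene was deleted is not given in the sources used here. ldhA had a signal of 792.4 on the wild-type array and 77.7 on the knockout array, which lay below the floor, so it was at least 5.07-fold lower in the knockout. pflB had signals of 476.0 and 138.1, the knockout value again below the floor, and was at least 3.04-fold lower. The log2 bound of pflB (-1.61) was under 2-fold with quantile normalization (-0.50), a doubled floor (-0.61) and loess (-0.78), and -1.01 with median centring; that of ldhA (-2.34) was -1.34 with a doubled floor, -1.52 with loess and -1.75 with median centring. With the hybridization and poly-A controls, scalings chosen after seeing the data, the bounds were -3.08 and -3.93 for ldhA and -2.34 and -3.20 for pflB. On the wild-type array these genes did not stand out from the rest, since ldhA lay at percentile 88.5 and pflB at percentile 36.8 of all gene signals; on the knockout array they lay at percentiles 3.04 and 12.2. Among the intergenic probe sets of the wild-type array, ldhA lay at percentile 93.0 and pflB at percentile 68.7. Without a floor the log2 ratios of ldhA and pflB were -3.35 and -1.79, at percentiles 0.68 and 11.6 of all genes. A fall as large as that of pflB was not rare, so alone it does not show the deletion. On the knockout array 614 of 4099 detected genes were below the floor, where signals have no order, so no exact rank can be given to either ratio. With the floor at percentile 90 of intergenic signals (803.2 on the knockout array), an alternative chosen after seeing the data, the floor lay above the wild-type signal of ldhA, so no fold can be given, and pflB was detected on neither array.

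The genes beside the targets differed from each other. focA, which lies next to pflB and encodes a formate channel, was 2.60-fold lower in the knockout (582.4 and 224.3). pflA, on the other side of pflB, encodes the enzyme that activates pyruvate formate-lyase and had a log2 ratio of 0.54 (451.3 and 656.8), which was -0.19 with the hybridization controls and -1.05 with the poly-A controls. hslJ and ydbH, which flank ldhA, were 3.08-fold and 2.47-fold lower. The median of all detected genes was lower by 0.75 on the log2 scale, so relative to it focA, hslJ and ydbH stood at -0.63, -0.88 and -0.56 and pflA at 1.29.

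Across the genome, 513 genes were at least 2-fold higher and 1603 at least 2-fold lower in the knockout, among 4099 genes detected on at least 1 array. The split of these genes was 24.2% higher and 75.8% lower. It turned with the scaling: with the arrays centred on the genes detected on both, 855 genes were higher and 440 lower (66.0% higher), and 622 and 498 with quantile normalization (55.5% higher). With loess the counts were 347 and 264 (56.8% higher), and with the hybridization controls set equal 244 and 2676 (8.36% higher). The hybridization scaling used the mean log2 ratio (0.74) of 4 probe sets that differed from each other. BioB was 2.84-fold higher on the knockout array, BioC 1.44-fold and CreX 1.35-fold and 1.39-fold. Transcripts of the strains' own bioB and bioC genes could add to the first 2, so this shift is uncertain. The 12 probe sets for added poly-A controls were all higher on the knockout array, by a median of 1.59 on the log2 scale without a floor. Their median signal on the wild-type array was 153.6, below the floor of 211.8, so this shift is uncertain. With the poly-A controls set equal, 107 genes were higher and 3374 lower (3.07% higher). Under that scaling, chosen after seeing the data, all list medians were below 0 except those of ribosomal proteins (1.87), ATP synthase (1.14), sulfate assimilation (0.73) and terminal oxidases (0.024). The percentiles of the lists among random lists were the same as with the deposited scaling, as they have to be when all ratios move alike. Of the 1603 lower genes, 501 were below the floor of the knockout array. With the floor raised to percentile 90 of the intergenic probe sets, 363 genes were higher and 25 lower among 1326 detected genes, of which 989 were above this floor on 1 array alone, so that their ratios are bounds. With the floor from deleted genes and the same threshold, 2528 intergenic probe sets were above the floor on at least 1 array. Of these, 254 were higher and 1134 lower on the knockout array, so such counts are not particular to genes. No test between strains could be made on any of these counts.

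The highest ratios belonged mainly to ribosomal protein genes. proW, a subunit of the ProU glycine betaine transporter, was at least 42.9-fold higher in the knockout, with a signal of 9093 there and 106.0, below the floor, on the wild-type array. ompT, an outer membrane protease, was 33.7-fold higher (504.5 and 17007). Among the 12 highest, 8 encode ribosomal proteins: rpsG (29.2-fold), rpsL (27.7-fold), rplR (25.1-fold), rplW (22.1-fold), rplE (19.6-fold), rpsN (19.0-fold), rpsE (18.7-fold) and rpsJ (log2 ratio 4.17). The others were aceB (20.8-fold), which encodes malate synthase of the glyoxylate shunt, and gatZ (17.9-fold) of galactitol catabolism. Of the 513 higher genes, 380 had wild-type signals at or under percentile 90 of the intergenic probe sets of that array (710.1), or 74.1%, against 79.7% of all genes.

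The lowest ratios, ranked with the floor applied, included several transfer RNA genes. Ratios of genes below the knockout floor are bounds, so the true order is not known. Without a floor, leuX, ytfH and atoA, named below, stood at percentiles 1.35, 2.10 and 2.34 of all ratios. proL was at least 22.0-fold lower in the knockout (3443 and 78.9), thrW 11.2-fold lower (20657 and 1849), trpT 11.4-fold lower (11582 and 1017), leuX 6.85-fold lower and leuZ at least 5.09-fold lower. The probe sets of proL, thrW and the insertion element gene insF4 (5.95-fold lower) are marked as shared with similar sequences, so these values are uncertain. The other genes were yhjY (at least 7.51-fold), murQ (at least 5.90-fold), ytfH (5.63-fold), atoA (5.47-fold), eutN (at least 5.34-fold) and zraP (at least 5.26-fold). Of these, murQ acts in the recycling of cell wall sugars and atoA in the breakdown of acetoacetate. All 6 had knockout signals of 160.2 or less.

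**Figure D2:**
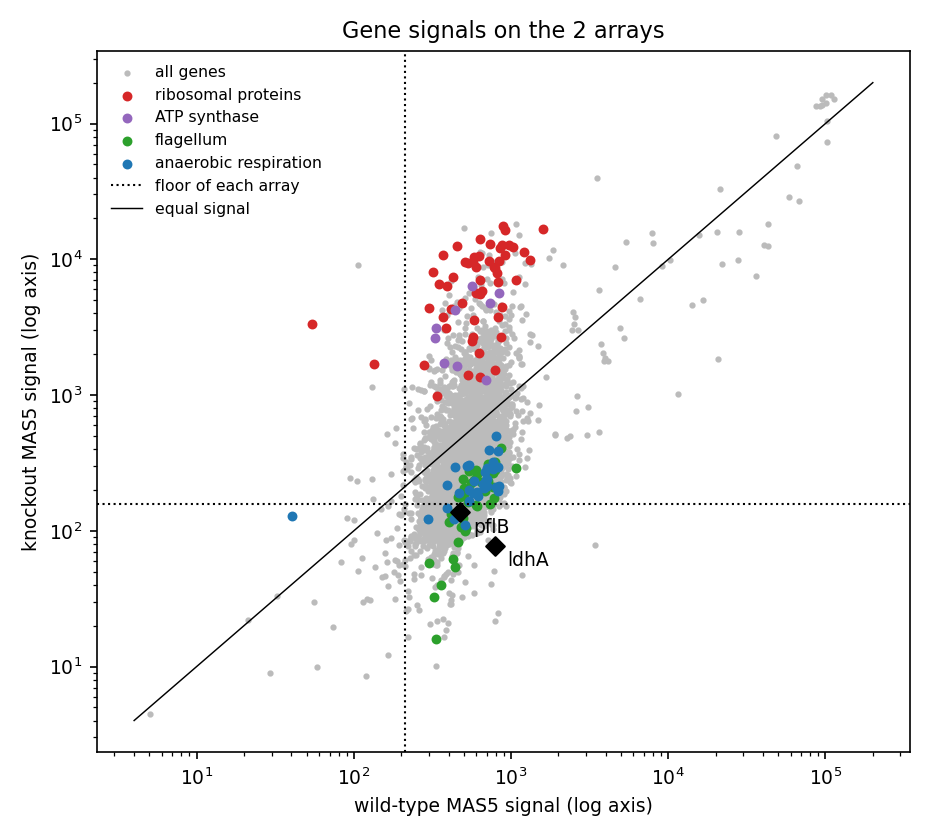
MAS5 signal of each gene on the wild-type array (horizontal, log axis) and the knockout array (vertical, log axis), with members of 4 gene lists coloured, the targeted genes as black diamonds, dotted floors and a line of equal signal. Most genes lie in a narrow vertical band on the wild-type array, in which ribosomal protein genes (medians 630.3 and 7260) lie above the line and flagellar genes (medians 541.8 and 176.7) lie near the knockout floor of 156.3.

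Ribosomal protein and ATP synthase genes had higher signals on the knockout array than on the wild-type array. With the narrow wild-type range, genes with high knockout signals tended to have high ratios, here and in other lists. The design cannot tell a strain difference from a difference between the arrays. Of 54 ribosomal protein genes, 53 were at least 2-fold higher, and the remaining gene, rpsQ, chosen after its value was seen, had a log2 ratio of 0.97. Their median ratio was 3.46 on the log2 scale, or 4.21 above the median gene, and lay at percentile 100 of matched random lists. Their median signal was 630.3 on the wild-type array and 7260 on the knockout array, and 22 of 54 on the wild-type array and 54 of 54 on the knockout array exceeded percentile 90 of the intergenic probe sets. All but 1 of the 9 ATP synthase genes were at least 2-fold higher, with a median ratio of 2.73 (percentile 99.97). atpE, of the membrane ring, was 11.2-fold higher and atpG 9.62-fold higher, while atpC, chosen after its value was seen, had a log2 ratio of 0.90. The medians of both lists stayed above 0 under every scaling run, and the lowest, with loess, were 0.68 for ribosomal proteins and 1.14 for ATP synthase. The scalings that move all ratios alike were too small to turn these signs. With the intergenic floor, at which 7 of 9 ratios are lower bounds, the ATP synthase list moved to percentile 97.2, just inside the random range.

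Of the lists of aerobic energy metabolism, those of the TCA cycle and of terminal oxidases lay above the random range and that of NADH dehydrogenase I inside it. The list medians were above 0 under each scaling run, except that with the poly-A controls the TCA cycle list stood at -0.19 and NADH dehydrogenase I at -0.33. On the wild-type array the median signal of the TCA cycle list lay at percentile 72.4 of the intergenic probe sets, and 2 of its 17 genes exceeded percentile 90. In the TCA cycle and glyoxylate shunt, 13 of 17 genes were at least 2-fold higher and none at least 2-fold lower, with a median of 1.40 (percentile 99.7). aceB was 20.8-fold higher, aceA, encoding isocitrate lyase, 13.2-fold, icd, encoding isocitrate dehydrogenase, 9.64-fold and sucB, of 2-oxoglutarate dehydrogenase, 5.17-fold. fumA and fumC, chosen after their values were seen, had log2 ratios of -0.25 and -0.41. Of 9 terminal oxidase genes, 6 were higher and 2 lower (median 1.62, percentile 97.8). cyoA and cyoB, of the cytochrome bo oxidase, were 6.31-fold and 6.14-fold higher and cydB, of the cytochrome bd oxidase, 3.18-fold higher. The lower genes, chosen after their values were seen, were appC and appB, of a further cytochrome bd oxidase, at -1.07 and -1.35 on the log2 scale. NADH dehydrogenase I had 7 of 13 genes higher (median 1.26, percentile 97.4), with nuoE at 3.75-fold. With the intergenic floor, at which 11 of 13 ratios are lower bounds, the TCA list (percentile 95.6) was inside the random range too. Of the 11 settings that can move a percentile, the main one included, the oxidase list was above the random range in 5 and NADH dehydrogenase I in 3. The lowest percentile of the oxidase list was 83.9, with the mean in place of the median.

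Glucose uptake and glycolysis stood at a median of 1.28, at percentile 96.6 of matched random lists, with 13 of 18 genes higher and none lower. The matched lists had a median of 0.70, against -0.75 for all genes, and among unmatched lists the percentile was 100; the list lay above the random range in 4 of the 11 settings that can move its percentile. Its median was above 0 under each scaling run except the one on poly-A controls (-0.31). gapA, encoding glyceraldehyde-3-phosphate dehydrogenase, was 16.8-fold higher, ptsH of the sugar phosphotransferase system 9.44-fold, pgk 8.03-fold and eno 7.62-fold. pfkA and pykA, chosen after their values were seen, had log2 ratios of 0.26 and -0.0057. The pentose phosphate and Entner-Doudoroff list had 2 of 11 genes higher, gnd at 4.01-fold and talA at 2.42-fold (median 0.21, percentile 25.5); with loess the median was -0.12 and talA stood at -0.17, and with the hybridization controls the median was -0.52. With the poly-A controls talA stood at -0.32. No gene of the gluconeogenesis and malic enzyme list differed by 2-fold (6 genes, median -0.039, percentile 22.9; median 0.56 with median centring).

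The genes closest to the deleted reactions went in different directions. In the list of formate and mixed-acid fermentation, 2 of 14 genes were at least 2-fold higher, 3 lower and 9 neither (median -0.23, percentile 52.2; median 0.36 with median centring). ppc, which makes oxaloacetate from phosphoenolpyruvate, was 6.51-fold higher. adhE, which makes ethanol, was 3.74-fold higher as deposited (872.1 and 3265) but had a log2 ratio of -0.37 with loess. fumB, an anaerobic fumarase, was 3.05-fold lower. The fumarate reductase genes frdA, frdB, frdC and frdD, chosen after their values were seen, had log2 ratios of 0.09, -0.30, at most -0.86 (knockout signal below the floor) and -0.88. ackA and pta, of acetate formation and chosen in the same way, had 0.33 and -0.66. Among 7 genes of pyruvate dehydrogenase and acetate use, aceF (4.61-fold), lpd (3.90-fold) and aceE (3.08-fold), the pyruvate dehydrogenase subunits, were higher and acs, an acetyl-CoA synthetase, 2.23-fold lower. With loess, aceE stood at -1.03 and lpd at -0.066, and with quantile normalization aceE stood at -0.21 and acs at 0.038. This list had a median of 0.19 (percentile 37.9), which was -0.066 with loess and -0.55 with the hybridization controls.

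Lactate and methylglyoxal metabolism had 1 of 10 genes at least 2-fold lower, lldD, a lactate dehydrogenase used in lactate oxidation, at least 3.21-fold, and none higher (median -0.44, percentile 93.7; medians 0.15, 0.12 and 0.090 with median centring, loess and quantile normalization). Of 18 genes for formate hydrogenlyase and hydrogenase maturation, 10 were lower and none higher, with a median of -1.12, which was at percentile 28.2 of matched lists, 1.18 with quantile normalization and 0.73 with a doubled floor. Relative to the median of all detected genes (-0.75), with the floor applied, 0 of the 18 were at least 2-fold lower. hycC was at least 3.34-fold lower and hycH 3.20-fold lower. Among 9 genes of NAD synthesis and transhydrogenases, pntA and pntB, the subunits of the membrane transhydrogenase, were 4.04-fold and 2.96-fold higher and nadB 2.34-fold lower (median 0.58, percentile 77.5, or 98.8 among unmatched lists; median -0.16 with the hybridization controls). With the poly-A controls pntB stood at -0.028.

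Genes of anaerobic respiration, hydrogen uptake and motility formed the lists below the random range. Of 32 detected anaerobic respiration genes, 25 were at least 2-fold lower and none higher (median -1.45, percentile 0.03). torC was 4.18-fold lower, nrfG 3.93-fold, narI 3.44-fold, and fdnI had a log2 ratio of -1.93. Of 14 uptake hydrogenase genes, 10 were lower (median -1.42, percentile 0.20), with hyaA at 4.18-fold. This list was below percentile 2.5 in 7 of the 10 settings that can move its percentile, the main one included, and its highest percentile was 31.5, with a doubled floor. In the flagellum list, 39 of 41 genes were lower (median -1.45, percentile 0), among them flhD, a subunit of the master regulator of flagellar genes, at 4.70-fold and fliD, the filament cap, at 4.45-fold. In chemotaxis, 9 of 11 genes were lower (median -1.44, percentile 1.81), with tap at least 4.05-fold and tar 3.75-fold lower. Relative to the median gene these medians were -0.70, -0.67, -0.70 and -0.69. The medians as deposited stayed below 0 under every scaling run, though only quantile normalization and loess could have turned their sign. Relative to the median gene, with the floor applied, 4 anaerobic respiration, 2 uptake hydrogenase, 7 flagellar and 3 chemotaxis genes were at least 2-fold lower. Among all detected genes 253 were.

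The median signals of these lists lay under percentile 90 of the intergenic probe sets on both arrays. The flagellum list had a median signal of 541.8 on the wild-type array and 176.7 on the knockout array, at percentiles 77.03 and 54.99 of the intergenic probe sets. None of the genes in these 4 lists exceeded percentile 90 of the intergenic probe sets on the knockout array. With the floor at that percentile, 9 flagellar, 9 anaerobic respiration, 4 chemotaxis and 3 uptake hydrogenase genes were detected, all on the wild-type array alone, so their ratios are upper bounds and neither a shift nor its loss can be read from them.

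**Figure D3:**
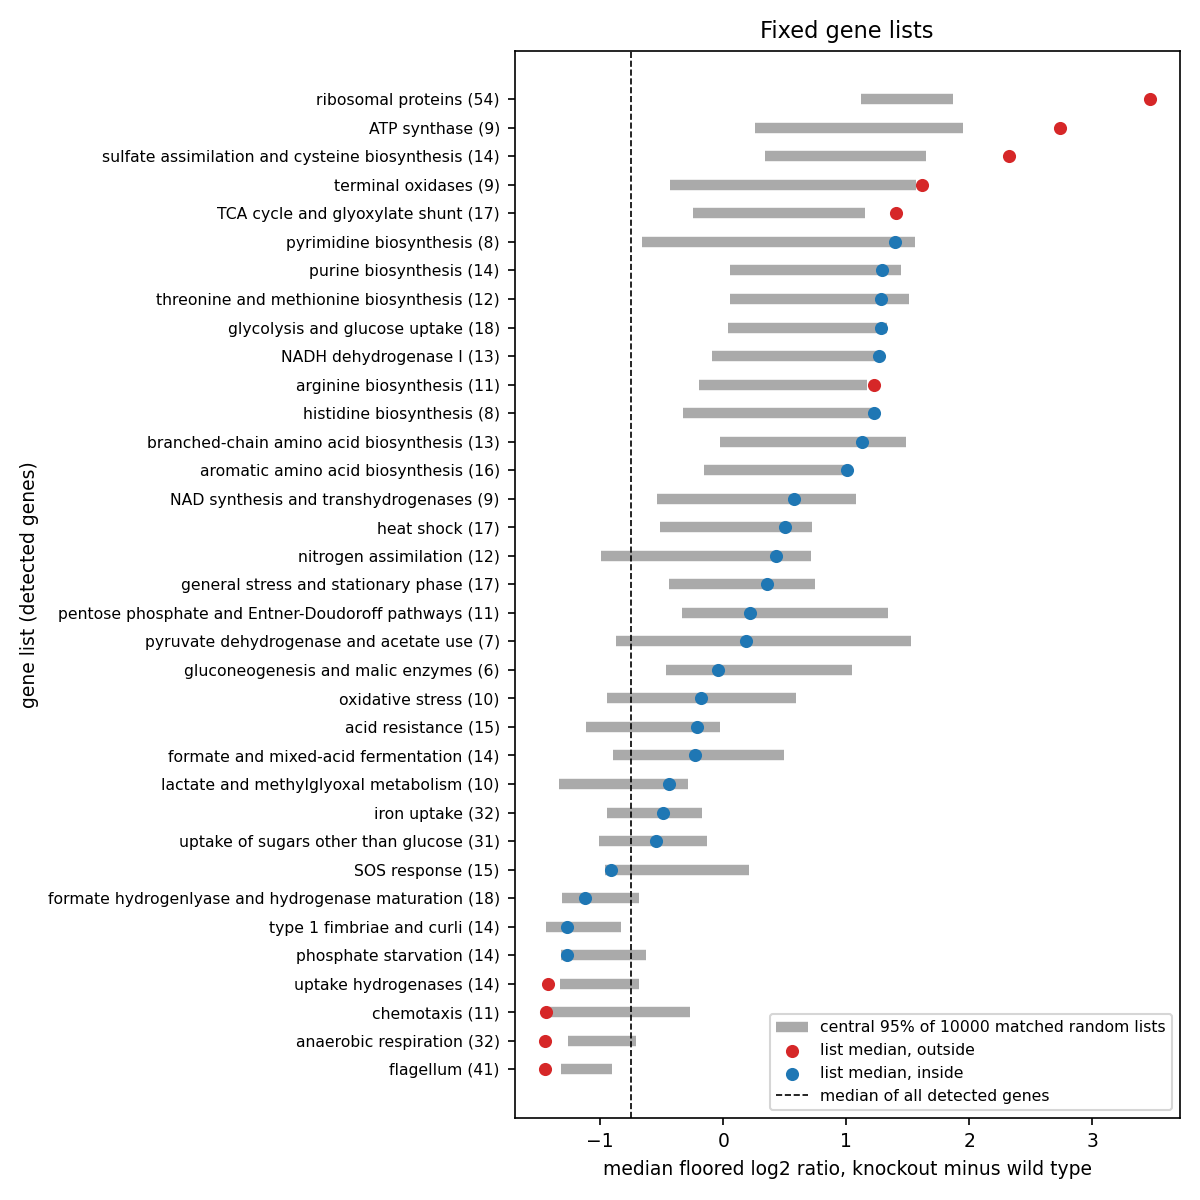
Median floored log2 ratio of each fixed gene list (points, horizontal axis; number of detected genes in parentheses) with the central 95% of 10000 random lists matched on signal (grey bars) and the median of all detected genes (dashed line, -0.75). Above the random range lie 6 lists (up to 3.46 for ribosomal proteins), and below it lie 4; red points mark lists outside the range and blue points lists inside it.

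The amino acid and nucleotide biosynthesis lists had medians above 0 under each scaling run except the one on poly-A controls, where the sulfate list alone stayed above 0 (0.73). Sulfate assimilation and cysteine biosynthesis had 11 of 14 genes higher and none lower (median 2.32, percentile 99.99), led by cysK, encoding cysteine synthase, at 10.9-fold and cysJ, of sulfite reductase, at 10.1-fold. Arginine biosynthesis had 6 of 11 genes higher (median 1.23, percentile 98.3), with argC at 5.81-fold and carB at 5.62-fold. Its percentile was 79.9 with the intergenic floor, at which 6 of 9 ratios are bounds, and carB stood at -0.49 with loess. The 6 lists that follow lay inside the range of matched random lists, and above the range among unmatched lists and with quantile normalization. Of the 11 settings that can move a percentile, pyrimidines were above in 5, branched-chain amino acids in 4, aromatic amino acids and purines in 3, and histidine and the threonine and methionine list in 2. Histidine biosynthesis had 5 of 8 genes higher (median 1.22, percentile 97.2), hisD by at least 5.37-fold. Branched-chain amino acids had 9 of 13 (median 1.13, percentile 86.5), with ilvC at 6.93-fold, and threonine and methionine 7 of 12 (median 1.29, percentile 91.3), with metE, a methionine synthase, at 11.9-fold. Aromatic amino acids had 8 of 16 (median 1.004, percentile 96.7), with aroK at 4.08-fold. Purines had 9 of 14 (median 1.29, percentile 93.3), with guaB at 5.93-fold. Pyrimidines had 5 of 8 higher and 1 lower (median 1.40, percentile 95.03), with pyrB, of aspartate transcarbamoylase, at 14.9-fold. In nitrogen assimilation 5 of 12 genes were higher and 2 lower (median 0.43, percentile 89.7, or 99.3 among unmatched lists; median -0.31 with the hybridization controls), with gltB, of glutamate synthase, 9.91-fold higher and glnK 3.04-fold lower.

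The stress, uptake and fimbriae lists were inside the range of matched random lists, and 7 of them left it under other settings. Among unmatched lists heat shock (percentile 99.8) and general stress (99.5) were above it and fimbriae (2.17) below. Sugars other than glucose were above it with loess (99.4) and with the mean in place of the median (97.98). Phosphate starvation was below it with quantile normalization (0.93), loess (1.91) and unmatched lists (1.87), the SOS list with unshared protein-coding probe sets (2.33) and iron uptake with the intergenic floor (0.29). The acid resistance list had 2 of 15 genes higher, the periplasmic chaperone genes hdeA (4.64-fold) and hdeB (3.06-fold), and 5 lower, among them cadA, a lysine decarboxylase, by at least 3.61-fold (median -0.21, percentile 90.6; medians 0.38, 0.21 and 0.44 with median centring, loess and quantile normalization). Heat shock genes had 4 of 17 higher and 3 lower (median 0.50, percentile 89.4; medians -0.16 with loess and -0.24 with the hybridization controls), with clpP at 2.82-fold and hslO 2.22-fold lower. General stress genes had 5 of 17 higher and 1 lower (median 0.36, percentile 78.1; median -0.38 with the hybridization controls), with elaB at 3.33-fold and rpoS at 2.98-fold. With the poly-A controls clpP stood at -0.097 and rpoS at -0.017. The SOS list had 2 of 15 higher and 6 lower (median -0.91, percentile 3.75), with dinB 3.49-fold lower. Oxidative stress genes had 3 of 10 higher and 1 lower (median -0.18, percentile 51.2; medians 0.42, 0.23 and 0.34 with median centring, loess and quantile normalization). Among them, sodB and ahpC were 5.26-fold and 4.97-fold higher, and grxA, a glutaredoxin, 4.31-fold lower. Iron uptake had 3 of 32 higher and 6 lower (median -0.49, percentile 66.99; median 0.10 with median centring), with exbB at 2.56-fold (-0.23 on the log2 scale with the poly-A controls) and fecD at least 3.76-fold lower. Phosphate starvation genes had none of 14 higher and 8 lower (median -1.27, percentile 6.17), with phoE 3.39-fold lower. Fimbriae and curli had none of 14 higher and 9 lower (median -1.27, percentile 31.5), with csgD 3.15-fold lower. Relative to the median gene, with the floor applied, the lower genes numbered 2 for phosphate starvation, 1 each for SOS and iron uptake, and 0 for fimbriae and curli. Among 31 genes for sugars other than glucose, 8 were higher and 8 lower (median -0.55, percentile 61.3; medians 0.048, 0.28 and 0.31 with median centring, loess and quantile normalization). gatZ, gatY, gatB and gatA of galactitol use were 17.9-fold, 16.7-fold, 9.91-fold and 9.07-fold higher.

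Adjacent genes, many of which share a transcript, were compared with random pairs. Over 2732 adjacent pairs detected on both arrays, the log2 ratios of neighbours had a Spearman rho of 0.53 across pairs, against -0.0065 for random pairs. The median absolute difference was 0.59 between neighbours and 1.003 between random genes. For the signals themselves, over 3789 adjacent pairs, rho was 0.08 on the wild-type array and 0.48 on the knockout array. The agreement of the ratios can therefore come from the knockout array alone, and it does not by itself show differences between the strains.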

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

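The tests below were set before their values were computed, though after the narrow range of the wild-type signals had been seen. Signal that differed between the arrays was also seen in probe sets outside the gene comparison. Of 2528 intergenic probe sets above the floor on at least 1 array, 254 were at least 2-fold higher and 1134 at least 2-fold lower on the knockout array than on the wild-type array. The 12 control probe sets for added poly-A transcripts (DapX, LysX, PheX and ThrX) were all higher on the knockout array, by a median of 3.01-fold (2.35-fold to 4.73-fold). Their median signal on the wild-type array (153.6) was below the floor. Whether these transcripts were added to both samples is not given in the sources used here.

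The genes higher in the knockout are set against a wild-type array on which signals spanned 3.22-fold for genes and 7.20-fold for intergenic probe sets between percentiles 5 and 95, against 27.6-fold and 43.9-fold on the knockout array. Background binding raised by scaling a weakly labelled array would lift foreign sequence too, but phage and F plasmid probe sets had 0.0631 times the intergenic median on the wild-type array, which argues against it. A different wild-type mRNA profile, measured as well as that of the knockout, would leave neighbouring genes in agreement, but their rho on the wild-type array was 0.159 times that on the knockout array. Labelled chromosomal DNA in the wild-type sample is a candidate explanation that stays open: the predicted fall in signal from replication origin to terminus was -0.0465 on the log2 scale (95% interval -0.17 to 0.077), an interval that spans the bound of -0.1 set for it. This interval and the next are taken across intergenic probe sets of 1 array, which are not replicates, so variation between arrays or cultures is left out. The knockout array, where no such DNA is proposed, had a fitted change of -0.81 (95% interval -1.02 to -0.60), so a fall of this kind does not single out DNA. Nor do the forward-strand and reverse-strand intergenic medians, which were near each other on the wild-type array (391.3 and 366.7) and on the knockout array (162.1 and 160.02). A difference between the strains other than such a well-measured profile stays open too, untested, because the strain and the array coincide in this design. Other technical differences between the samples or arrays were not tested either, so the explanations named here are not a full list.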

How the results depend on the processing

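The intergenic floor, the scalings on hybridization and poly-A controls and the unshared protein-coding probe sets were chosen after seeing the data. No paired analysis was possible because each strain has 1 array. The count of higher genes (513) moved to 855 with median centring, 244 with the hybridization controls and 107 with the poly-A controls, and the count of lower genes (1603) to 440 with median centring, 498 with quantile normalization, 264 with loess, 526 with a doubled floor, 25 with the intergenic floor, 2676 with the hybridization controls and 3374 with the poly-A controls. The lists above the random range (6) became 13 with quantile normalization, 10 with loess, 18 with unmatched random lists and 3 with the intergenic floor, and those below (4) became 1 with the intergenic floor, the iron uptake list (percentile 0.29); at this floor 10 of its 13 ratios and all ratios of the former 4 lists are bounds. The ratio of ldhA (-2.34) was -1.34 with a doubled floor, -3.35 with no floor, -3.93 with the poly-A controls and at most 0.0197 with the intergenic floor, a bound whose sign the floors fix; that of pflB (-1.61) was -0.50 with quantile normalization, -0.61 with a doubled floor, -0.78 with loess and -3.20 with the poly-A controls. Neither has a value among genes detected on both arrays, nor pflB with the intergenic floor. The rho of neighbouring ratios (0.53) was 0.37 with quantile normalization and 0.25 with loess. Median centring and the scalings on controls move all ratios alike and so leave list percentiles as they are. Of the 11 other settings, the main one included, the ribosomal protein and sulfate lists lay above the random range in 11, ATP synthase and TCA in 10, arginine in 8 and terminal oxidases in 5. The anaerobic respiration and flagellum lists lay below it in 10, all but the intergenic floor, chemotaxis in 10 of 10 and uptake hydrogenases in 7 of 10. The median over detected genes moved from -0.75 to -0.15 with median centring, -0.0017 with quantile normalization, -0.15 with loess, -1.48 with the hybridization controls, -2.34 with the poly-A controls, -0.50 with a doubled floor and 0.33 with the intergenic floor. Over 161 genes named by the rule, apart from the targets, and 1703 alternative values, 57 changed sign, 35 of them of ratios of at least 2-fold. Of the remaining values, together with the 22 of smaller ratios that changed sign, 1335 moved by less than the spread between genes (0.97) and 333 by more. Many of these moves were fixed by the setting, so the counts do not measure robustness. Median centring and the hybridization controls (0.74) shift every ratio by less than 0.97, and the poly-A controls (1.59) by more. Restricting to genes detected on both arrays leaves a ratio as it is. With loess the 2-fold ratios that changed sign were aceE (-1.03), adhE (-0.37), aroA (-0.23), carA (-0.57), carB (-0.49), dps (-0.22), gltD (-0.62), groS (-0.52), lpd (-0.0658), nuoC (-0.65), purC (-0.60), purN (-0.0492), talA (-0.17), thrC (-0.88), uspA (-0.34) and yebG (-0.54). With the poly-A controls they were aroA (-0.20), aroF (-0.12), clpP (-0.0974), dps (-0.50), exbB (-0.23), hisC (-0.33), hslV (-0.27), pntB (-0.0282), rpoS (-0.0173), sodA (-0.25) and talA (-0.32). With quantile normalization they were aceE (-0.21) and acs (0.0384). With the intergenic floor they were fdnI (0.00057), flhD (0.13), fliD (0.0526), hyaD (0.10), hycH (0.0628) and leuZ (0.0144), each an upper bound, since the knockout signal was below that floor. The smaller ratios that changed sign were aldA (0.18), edd (-0.19), fbp (-0.65), gloB (0.0615), lldR (0.22), maeA (-0.48) and talB (-1.20) with loess, aldA (0.0833), fbp (-0.53), gloB (0.59), lldR (0.0969), maeA (-0.20) and talB (-0.73) with quantile normalization, fbp (-0.67), maeA (-0.33) and pflA (-0.19) with the hybridization controls, and edd (-0.62), fbp (-1.52), maeA (-1.18), nadE (-0.72), pflA (-1.05) and talB (-0.83) with the poly-A controls. Of the genes of fixed lists chosen after their values were seen, fumA, fumC, rpsQ, atpC, pfkA, pykA, frdA, frdB, frdC, frdD and ackA changed sign under at least 1 scaling, taken without a floor, and pta, appB and appC did not. Beyond the raised floors, the causes of these moves were not tested. Signal over background limits both arrays: of 4148 genes, 840 (20.3%) on the wild-type array and 823 (19.8%) on the knockout array exceeded percentile 90 of the intergenic probe sets.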

Other observations

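The genes and RNA classes in this part were chosen after their values were seen. The other genes of the glycine betaine transporter, proV and proX, were 12.6-fold and 10.2-fold higher in the knockout, beside proW. The outer membrane protein genes ompC and ompA were 17.2-fold and 11.8-fold higher. The cold shock family genes cspE, cspC and cspA were 13.5-fold, 12.2-fold and 11.3-fold higher. acpP and fabG, of fatty acid synthesis, were 12.6-fold and 11.5-fold higher, and serA and glyA, of serine and glycine synthesis, 10.8-fold and 10.4-fold higher. On the wild-type array these 11 genes lay at percentiles 47.4 (fabG) to 99.7 (cspA) of the intergenic probe sets. On the knockout array they lay at percentiles 97.7 to 99.8. With the narrow wild-type range, high knockout signals tended to give high ratios, so these folds are not read as induction. The log2 ratios of these 11 genes stayed above 0 under each scaling run, and with loess they ran from 0.097 (cspE) to 1.96 (fabG). Only quantile normalization and loess could have turned a sign here. The other scalings move all ratios alike, by at most 1.59, and the smallest of these ratios was 3.35 (proX). rpoA, chosen in the same way and 10.5-fold higher as deposited, stood at -0.096 with loess.

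Of 18 ribosomal RNA probe sets, which share sequence between operons, 16 had log2 ratios above 0, with a median of 0.54. The sign turned with the scaling: the median was 0.047 with quantile normalization, -0.20 with the hybridization controls, -0.25 with loess and -1.06 with the poly-A controls. Of 48 transfer RNA genes, 15 had ratios above 0, with a median of -0.87, near the median over all genes without a floor (-0.78). Of the 18 with unshared probe sets 5 did, with a median of -1.32. The nearness to all genes was lost under 2 scalings. With quantile normalization the medians were -1.53 for the 48 genes and -0.95 for the 18, against -0.086 for all genes. With loess they were -2.53 and -1.28, against -0.20. The small stable RNA genes ffs, of the signal recognition particle, and ssrA, the transfer-messenger RNA, had log2 ratios of -2.27 (36022 and 7490) and -1.02 (58524 and 28807), which stayed below 0 under each scaling run. Only quantile normalization and loess could have turned these signs.

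lacZ, which is also affected by a deletion in BW25113, had a signal of 906.2 on the wild-type array and 206.2 on the knockout array.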
